A study of Arabidopsis thaliana with 10 samples.

How the data were processed

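RNA from Arabidopsis inflorescences was measured on 10 cDNA arrays with 2 channels each, 2 arrays at each of 0, 4, 8, 10 and 16 h. Per the labels, each array compared plants given dexamethasone with plants given a control solution for the same time. The array numbered 1 carried the dexamethasone sample in channel 1 and the array numbered 2 carried it in channel 2. The labels do not say whether the 2 arrays of a time used separate plants or the same RNA. The p-values therefore measure the spread between these arrays, which may be technical only, and the number of arrays limits the precision. In the fit without the block described below, that spread also holds the dye effect of each probe.

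The authors deposited 1 signed log ratio of the channels per probe and array, read here as log10 values. The base is not stated. Base 10 is likely because the values stop at exactly 2 and -2, which is 100-fold in base 10 and 4-fold in base 2, and because only 2 values over all arrays lay between 1.5 and 2 in size. Folds below hold only if the base is 10. The channel in the numerator is not stated either. The column medians lay between 0.00314 and 0.0165, so the deposited arrays look centred. The scanner, dyes, background correction and normalization are not given in the sources used here. Column totals or spot intensities are not used here, so signal over background is unknown.

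The table held 10816 probes. The plate and well were read from the probe identifiers, which is an inference from their form and gives 114 plates. The files do not pair the probes with genes, and the table of gene names matched no identifier. The gene lists, the tests of lists, the mean of all probes of a gene and the check of direction on known genes, all fixed before the data were examined, were therefore not run.

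Values at exactly 2 or -2 were treated as not measured. That choice was made after the values were seen and before any model was fitted, and counts with these values kept are given with the alternatives. A probe entered a comparison if it was measured on both arrays of each time compared and on at least 8 of the 10 arrays. Each ratio was turned by the labelled channels, so that the arrays numbered 2 changed sign. Values on the positive side and the negative side of 0 below refer to these turned ratios. Whether the positive side means a higher level with dexamethasone or a lower one is not known, and the other numerator would swap the sides.

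The rule for the turning was fixed before the data were examined. It named as treatment the part of the values whose variance rises from 0 h to the treated times, and as dye the part present at 0 h and correlated over times. Both variances rose, and that of the unturned mean rose more at every treated time, so that this part of the rule taken alone points to the other orientation. The variance of the turned mean of a pair went from 0.00751 at 0 h to between 0.00772 and 0.0102 at the treated times, and that of the unturned mean from 0.00713 to between 0.00989 and 0.0116. The part of the rule on correlation with 0 h points to the turning used here, with the values given in the report. The 2 parts disagree, and the turning is a choice between them. The variance part cannot decide, since the 2 arrays of 0 h correlated at -0.0271. That makes both variances at 0 h about equal, whichever part holds the dye effect.

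Models were fitted with limma 3.58.1 in R 4.3.3, with lmFit and eBayes, 1 coefficient per time and all 10 arrays in 1 fit. Tests were two-sided, with Benjamini-Hochberg adjustment over the probes of a comparison and a threshold of 0.05. The comparisons were each time against 0, the mean of the 4 treated times against 0, each treated time minus 0 h, successive treated times, and a slope over hours. Descriptions used pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1, and plots matplotlib 3.10.9.

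The replicate number marks the channel orientation in the labels. It was checked whether the numbers pair the arrays: the unturned means of a pair correlated between times at 0.252 to 0.549 in all 10 pairs of times. The numbers were taken to pair the arrays, and a fit with the number as a block, which is a dye effect per probe, is given wherever it changed a call or moved a count by over 1.5 times.

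The models were tested on simulated data with 200 changed probes and the missing values of the real table. A single residual spread for all probes and the size of a dye effect shared by every array were set from the real table. The simulation held no effect peculiar to an array number and no array without the dye effect. It therefore does not test the fits against these. For the mean of the 4 treated times over 10523 probes, the fit without the block recovered 64.3% of changes of 0.2 and 100% of changes of 0.4, with 0 unchanged probes called. With the block it recovered 99.0% and 100%, with 10 unchanged probes called. At 16 h over 10567 probes, the fit without the block recovered 0% and 31.6%, and with the block 36.4% and 98.9%, with 0 unchanged probes called without the block and 10 with it.

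The rule for named genes, fixed before the data were examined, needs a gene name and could not be used. In its place the 2 lowest and the 2 highest means over the treated times are named, among probes past the threshold that lay on 1 side on all 8 treated arrays. This rule was chosen after the values were seen, and 13 probes described in the report were left out of it. The alternatives were 2 centrings or scalings, the block, 2 other rules for missing values, robust eBayes, array weights, only the arrays compared, a 2-fold minimum, the other orientation, and each array left out in turn. Further alternatives were chosen after seeing the data: the limits kept, centring by position of the well, fits without 1 or both 0 h arrays, fits without 2 versions of the set of 13 probes, and the block with the other orientation.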

Results

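The arrays measured transcripts in inflorescences of Arabidopsis plants that lack a working AGAMOUS gene (ag-1) and carry 35S::AG-GR, a fusion of AGAMOUS to the steroid-binding part of the glucocorticoid receptor. AGAMOUS is a MADS-domain transcription factor that specifies stamens and carpels, and dexamethasone lets such a fusion enter the nucleus. Each array set RNA of plants treated with dexamethasone against RNA of plants treated with a control solution for the same time. There were 10 arrays, 2 at each of 0, 4, 8, 10 and 16 h, with the channels exchanged between the 2 arrays of a time. The cDNA array was enriched for transcripts of flowers. Of 10816 probes, between 10128 and 10670 were measured per array, 10592 on at least 8 arrays and 9859 on all 10. Values are log ratios, turned so that every array runs the same way, and folds assume base 10. The sign of the steroid's effect is unknown, so that results are given as positive and negative side. The files do not pair probes with genes, and no gene is named.

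The 2 arrays of a time shared a part of 1 sign on both and a part of opposite sign, and the latter is where the labels place the treatment. After turning, the 2 arrays of a treated time correlated over probes at -0.168 to -0.0216, and between 42.2% and 43.0% of probes had 1 sign on both. The mean of a pair without turning, which holds a dye effect, correlated at 0.455 to 0.549 between treated times and at 0.252 to 0.327 with 0 h. The turned mean correlated at 0.424 to 0.616 between treated times and at 0.000797 to 0.0444 with 0 h. The part absent at 0 h and shared by the treated times was taken as the treatment. The variance of the unturned mean rose more from 0 h than that of the turned mean, which by the rule points the other way. That rise cannot decide. The 2 arrays of 0 h correlated at -0.0271, which makes both variances at 0 h about equal, whichever part holds the dye effect. Against the second 0 h array alone, the unturned means of the treated times had r of 0.415 to 0.470. Their turned means had r of -0.0790 to -0.0257. These values rest on 1 array, and an effect of well position that was larger on arrays numbered 2 may enter them. The orientation is thus not settled. Probes are not independent replicates, and no p-value is attached to these correlations. The first 0 h array stood apart from the other 9, with r between -0.0367 and 0.0479, so that the comparison with 0 h rests largely on the second. Treated arrays of 1 number correlated at 0.362 to 0.500 for number 1 and at 0.595 to 0.702 for number 2, and those of different numbers at -0.0626 to 0.179 (median 0.0199). Effects peculiar to an array number would also make the turned means of different times correlate, so that these correlations do not by themselves show a treatment.

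**Figure D1:**
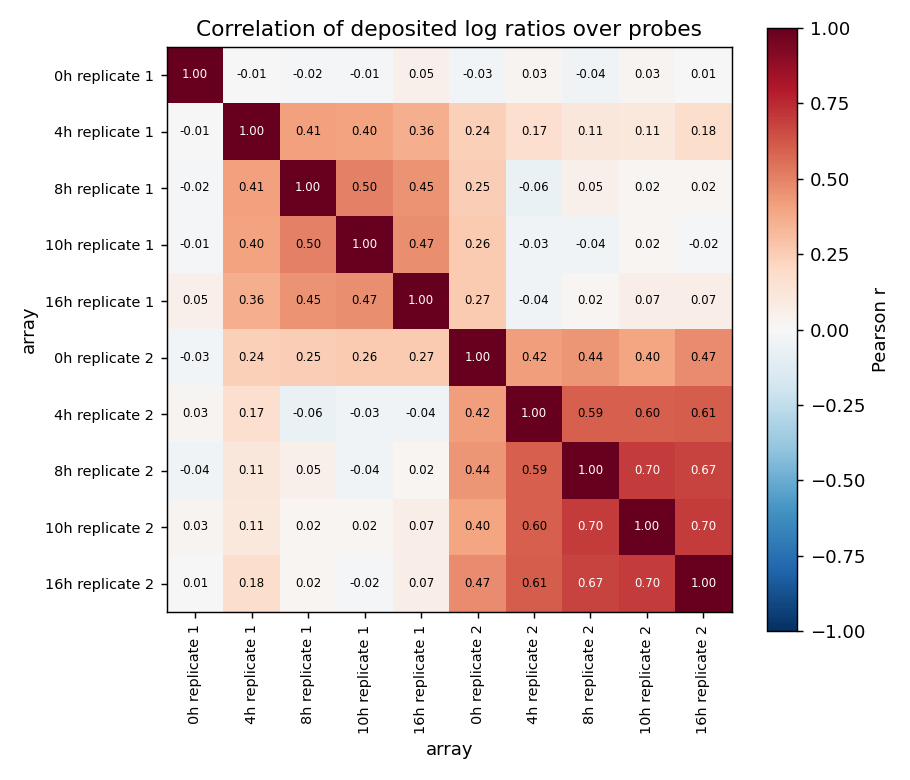
Pearson correlation over probes of the deposited log ratios, without turning, for each pair of the 10 arrays, ordered by array number and hours on both axes (colour, r). Treated arrays numbered 2 correlated at 0.595 to 0.702 with each other, and the first 0 h array at -0.0367 to 0.0479 with the other 9.

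The first question was which probes differed between dexamethasone and control solution over the 4 treated times. The mean of 4 to 16 h differed from 0 for 189 of 10523 probes (limma, adjusted p under 0.05), 58 on the positive and 131 on the negative side. Their sizes ran from 1.36-fold to 9.58-fold with a median of 1.76-fold, 1.59-fold on the positive and 1.91-fold on the negative side. Without the set of 13 probes set apart below, the largest was 4.01-fold. A change of at least 2-fold was reached by 49 of them, 48 negative and 1 positive. With the array number as a block, 905 probes passed, 450 positive and 455 negative, and all 189 were among them. The excess of the negative side in the count was thus not kept with the block. In a fit of the treated arrays alone, 130 probes passed, 124 of them among the 189. The 0 h arrays enter this mean only through the estimate of spread, so that the count depends in part on them. The count also depends on the turning: with the other orientation, 987 probes passed, 656 positive and 331 negative and none of them among the 189, and with the block as well 2357, 1530 positive and 827 negative. Leaving out single arrays lowered the count to between 41 and 147, and keeping the values at the limits lowered it to 88.

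Outside the set of 13, probe GP011D5 had the lowest mean, -0.603 (SE 0.0488, n = 8 arrays, 4.01-fold, limma adjusted p = 0.0017). It moved from -0.168 ± 0.112 (SD, n = 2) at 0 h to -0.316 ± 0.0971 at 4 h and -0.737 ± 0.0596 at 8 h, and stood at -0.756 ± 0.309 at 16 h. Probe GP062A4 had a mean of -0.574 (SE 0.0565, 3.75-fold, limma adjusted p = 0.0032), with -0.0745 ± 0.0357 (SD, n = 2) at 0 h and -0.795 ± 0.0753 at 8 h. On the positive side, GP001F5 had a mean of 0.309 (SE 0.0590, 2.04-fold, limma adjusted p = 0.032), with -0.0601 ± 0.122 (SD, n = 2) at 0 h and 0.438 ± 0.319 at 16 h. Its call was lost in 13 of 32 alternatives, some of which repeat the same result for the mean. With the other orientation the calls of all 4 probes named here were lost. Probe GP120H2 had a mean of 0.273 (SE 0.0351, 1.87-fold, limma adjusted p = 0.0092), with -0.0210 ± 0.0569 (SD, n = 2) at 0 h and 0.408 ± 0.142 at 16 h. These 4 probes were chosen after their values were seen.

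**Figure D2:**
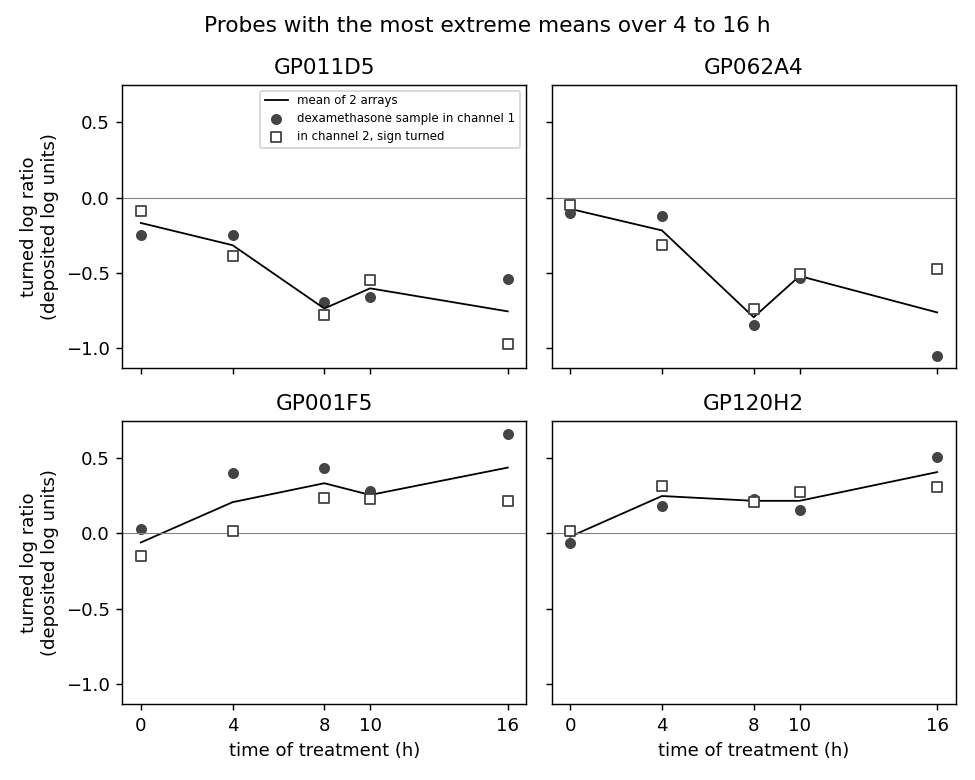
Turned log ratio in deposited log units against hours of treatment for 4 probes, with 1 symbol per array (filled, dexamethasone sample in channel 1, open, in channel 2) and a line through the mean of the 2 arrays. The 2 probes of the upper row reach means of -0.737 and -0.795 at 8 h, and those of the lower row 0.438 and 0.408 at 16 h.

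A set of 13 probes is set apart because of its ratios at 0 h. They were picked as at least 2-fold on 1 side at all 4 treated times and of 1 sign on both 0 h arrays. They lie in 2 plates that hold 192 probes, and all were on the negative side at the treated times. Most lie in runs of neighbouring wells, GP004C5 to GP004C9 and GP005D2 to GP005D7, so that the 13 may not count as separate. The shared sign of their deposited ratios at 0 h was positive for all 13, with medians of 0.653 and 0.616 on the 2 arrays. As labelled, the 0 h ratio thus went with the channel, but if the sign of the first 0 h array were turned, it would go with the sample as at 4 to 16 h. Of the 13, 9 are among the 189 called probes. The set was defined after the values were seen.

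**Figure D3:**
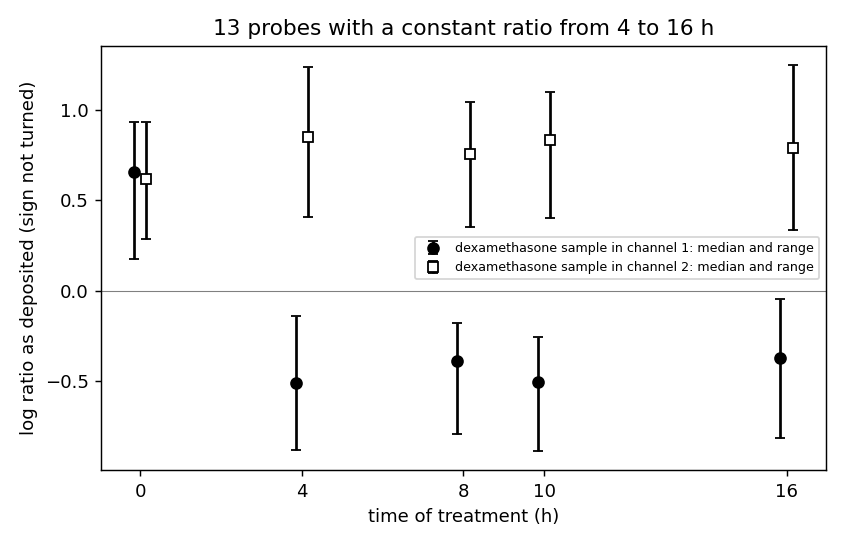
Deposited log ratio, without turning, against hours of treatment for the 13 probes, as median and range over the probes for each array (filled, dexamethasone sample in channel 1, open, in channel 2). The probes were picked by their side at 4 to 16 h and by a shared sign at 0 h. At 4 to 16 h the 2 arrays of a time have opposite signs, and at 0 h the medians are 0.653 and 0.616, both positive.

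Without these 13, 180 called probes were followed over the hours. The 122 on the negative side had a mean of 0.0412 ± 0.0307 (SD, n = 2 arrays) at 0 h, -0.164 ± 0.0876 at 4 h, -0.325 ± 0.00147 at 8 h, -0.292 ± 0.0435 at 10 h and -0.333 ± 0.0988 at 16 h. The 58 on the positive side had 0.0114 ± 0.00863 (SD, n = 2) at 0 h, 0.149 ± 0.0107 at 4 h, 0.231 ± 0.0541 at 8 h, 0.239 ± 0.0287 at 10 h and 0.212 ± 0.0410 at 16 h. These probes were picked from the treated arrays, which makes their treated means larger than those of an unpicked set. On all 8 treated arrays, 140 of the 180 lay on 1 side, 46 positive and 94 negative. The size of the set's mean was not shown to follow hours over the 8 treated arrays. Pearson's r was 0.633 on the negative side (exact permutation p = 0.0909, adjusted 0.300) with Spearman's rho 0.537 (exact permutation p = 0.190, adjusted 0.300). On the positive side r was 0.438 (exact permutation p = 0.279, adjusted 0.300) and rho 0.439 (exact permutation p = 0.300, adjusted 0.300). With hours exchanged only within an array number and values centred by number, r was 0.634 on the negative side (exact permutation p = 0.118, adjusted 0.300) and 0.520 on the positive side (exact permutation p = 0.233, adjusted 0.300). On the negative side r was 0.888 for the arrays numbered 1 and 0.189 for those numbered 2, and on the positive side 0.563 and 0.487, over 4 arrays each, too few for a test of their own. The number of relations tested was 6. Without the 16 h arrays, r was 0.750 and 0.822 over 6 arrays. Without the 4 h arrays it was 0.160 and -0.298, so that any rise over both array numbers together rests largely on the 4 h arrays. The numbers differed on the negative side. At 8, 10 and 16 h the mean was -0.3244, -0.2615 and -0.4024 for number 1, and -0.3265, -0.3229 and -0.2626 for number 2. On the positive side the mean was lower at 16 h than at 8 h for each number.

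**Figure D4:**
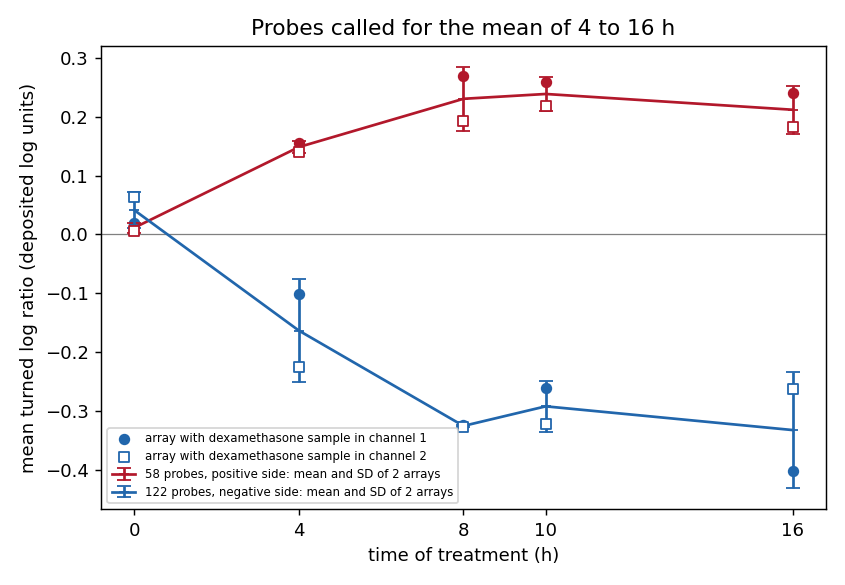
Mean turned log ratio in deposited log units against hours of treatment for the 122 called probes on the negative and 58 on the positive side, with 1 symbol per array and the mean and SD of 2 arrays as line and bars. The negative set goes from 0.0412 at 0 h to -0.164 at 4 h and -0.325 at 8 h, and the positive set from 0.0114 to 0.149 and 0.231.

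The second question was which probes differed at each time. By limma, 0 probes passed at 0, 4, 8 and 10 h, with 196, 296, 452 and 504 probes at an unadjusted p under 0.05, and 447 at 16 h. All lie below 5% of the probes tested, which is 496 at 0 h, 529 at 4 h and 528 at 8, 10 and 16 h. The fit without the block counts a dye effect per probe as spread, which raises its p-values. Its low counts thus do not show that nothing changed. With the block the counts were 493 at 0 h, below 5%, and 813, 983, 1095 and 1060 at 4, 8, 10 and 16 h, above it. In fits of only the arrays compared, 17 passed at 4 h, 23 at 8 h, 53 at 10 h and 32 at 16 h. At 16 h 1 probe passed in the fit of all arrays. This probe, GP011D4, lies in the well next to GP011D5, so that these may not count as separate. It was called on the negative side, at -0.815 (SE 0.0838, limma adjusted p = 0.030). That call was lost in 15 of 32 alternatives, among them 9 of the 10 fits that left out 1 array. With the block 0 probes passed at 0 h and 4 h, 22 at 8 h (1 positive and 21 negative), 2 at 10 h (both negative) and 48 at 16 h (13 positive and 35 negative). With the block and the limit values kept, 0 passed at 4, 8, 10 and 16 h, so that these calls depend on leaving out the limits, a choice made after the values were seen. With the block and without the first 0 h array, 11 passed at 4 h. On the negative side, 13 probes were called with the block at both 8 h and 16 h, where independent lists would share 0.0697. Both times share an estimate of spread per probe, and an effect peculiar to an array number would enter both. Part of the excess may come from these.

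The differences of each treated time from 0 h, and of successive treated times, gave 0 calls by limma. At an unadjusted p under 0.05 stood 179 probes for 4 h minus 0 h, 250 for 8 h, 312 for 10 h and 261 for 16 h, and 86, 39 and 60 for 8 h minus 4 h, 10 h minus 8 h and 16 h minus 10 h. All lie below 5% of the probes tested, which is 494 or 495 for the differences from 0 h and 527 or 528 for the successive times. Here too a dye effect per probe is counted as spread. With the block the counts were 606, 667, 749 and 689 for the differences from 0 h, above 5%, and 241, 156 and 257 for the successive times, below it. The first 0 h array does not carry the dye effect that the others share, so that turning does not cancel that effect at 0 h. The differences from 0 h and the slope over hours may thus hold part of it, and the excess over 5% may come from this. The slope over hours gave 0 calls of 10592 probes, with 399 at an unadjusted p under 0.05, where 5% is 530, and with the block 754. With the block, 16 h minus 0 h and the slope each gave 2 calls, both negative. They are the same 2 probes, which are also the 2 called at 10 h with the block. They lie in neighbouring wells of a plate that holds some of the 13 probes, so that they may not count as separate. A probe that passed at 1 time and not at another is thus not shown to differ between them. Without the second 0 h array, between 48 and 56 probes passed for a treated time minus 0 h, where the first 0 h array is the lone 0 h sample and is assumed to vary like the others.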

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

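All tests of explanations in this part were chosen after the values they bear on were seen. Values at the limits of 2 and -2 were left out of the comparisons of the report and stood in every array. There were 676 on 0 h replicate 1, 25 on 0 h replicate 2, 26 on 4 h replicate 1, 18 on 4 h replicate 2, 219 on 8 h replicate 1, 19 on 8 h replicate 2, 43 on 10 h replicate 1, 26 on 10 h replicate 2, 47 on 16 h replicate 1 and 16 on 16 h replicate 2. On 8 h replicate 1, 188 of the 219 lay at the positive limit in a group of 218 wells at repeating positions of the plates, where 8 other arrays held 91.1% of their missing values. No group had 4 or more arrays, so none was tested for a single array far from the rest.

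The first pattern is the first 0 h array, whose r over all probes lay near 0 with each of the others. A displacement of all its rows by the same number is argued against, for shifts of up to 500 rows. The largest size of r over these was 0.0815, against a median of 0.331 for the other 0 h array in place. Another order of its rows was not tested and stays open. In the group of 218 wells named above, 6.42% of its values were missing or at a limit, against 6.36% elsewhere. On the other arrays the share in these wells was 61.9% to 88.5%. A turned sign alone is argued against as the cause of r near 0, since outside the 2 plates of the 13 probes r ran from -0.0744 to 0.0636, where an array that differed only in sign needs values below -0.2. A turned sign beside another fault is not argued against, since an array without the shared signal gives r near 0 whichever way its sign runs. A weak or failed channel goes with its 676 limit values, of which 100% were positive. Whether it also accounts for the low share in the 218 wells was not tested. What happened to that channel stays open, and no biological explanation was tested. The array may nevertheless hold some signal, since in the 2 plates of the 13 probes its r was 0.607 to 0.707 with the arrays numbered 2 and -0.438 to -0.291 with those numbered 1. That is what a turned sign gives, but also what probes whose 0 h ratio goes with the channel give. Without the 13 probes and the 14 picked at 0 h, r over the other 177 probes of these plates was 0.1084 to 0.2001 with number 1 and 0.0585 to 0.170 with number 2. The negative r thus rests on the probes left out, and the sign of this array stays open.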

How the results depend on the processing

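Alternatives chosen after seeing the data are those with the limits kept, centring by position, fewer 0 h arrays with the block, the sets of probes left out, and the block with the other orientation. The cause of each change below was not tested, except that the 2-fold minimum and the sets left out remove probes by construction. Counts are probes past the threshold, against 189 for the mean, 1 at 16 h and 0 elsewhere. For the mean, 14 of 32 alternatives gave a count within 1.5 times of 189 and 18 did not. These alternatives are not all separate checks. For the mean, only the arrays compared and leaving out either 0 h array gave the same result. The block with fewer 0 h arrays likewise gave the same result each time. For the other comparisons the first count is 0 or 1, so that such a ratio does not exist or rests on 1 probe. Signal over background is unknown.

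Scaling each array gave 4 at 16 h and 2 for the slope. Array weights gave 0 at 16 h and 5 for the slope. Only the arrays compared gave 17 at 4 h, 23 at 8 h, 53 at 10 h and 32 at 16 h. The 2-fold minimum gave 49 for the mean. The other orientation gave 0 at 16 h and 987 for the mean, and turned GP011D5 to 0.0684 (limma adjusted p = 0.85) and GP120H2 to -0.00332 (0.99). It brought GP062A4 to -0.0640 (0.86) and GP001F5 to 0.137 (0.42). With the replicate block, the other orientation gave 1 at 0 h, 4 h and 10 h, 0 at 16 h, 2357 for the mean and 1 for each treated time minus 0 h, with GP011D5 at 0.0684 and GP120H2 at -0.00331. The treatment calls thus rest on the choice of orientation. Calls of the other orientation are calls of the unturned mean, which would hold a dye effect if the values are ratios of the channels.

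The replicate block, which pairs the arrays by number, gave 22 at 8 h, 2 at 10 h, 48 at 16 h, 905 for the mean and 2 each for 16 h minus 0 h and the slope, and changed no other call. It gave 22, 2, 46, 893, 2 and 2 without the 13 probes, and 22, 2, 46, 898, 2 and 2 without the 14. Centred by position it gave 13, 2, 47, 789, 2 and 8, and centring without the block gave 5 at 16 h and 2 for the slope. With the limits kept, the counts were 2 at 0 h, 0 at 16 h, 88 for the mean and 2 for each treated time minus 0 h. With the block as well they were 2, 0, 303 and 2, with 2 for the slope, and the 22 calls at 8 h and 2 at 10 h of the block went to 0. All 88 were among the 189, and 169 of the 303.

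With the block and without both 0 h arrays, 11 passed at 4 h, 36 at 8 h, 21 at 10 h, 59 at 16 h and 1016 for the mean. Without 0 h replicate 1 these were 11, 36, 22, 60 and 1016, with 8 at 0 h, 3, 2, 3 and 3 for 4, 8, 10 and 16 h minus 0 h, and 2 for the slope. Without 0 h replicate 2 they were 11, 36, 22, 60 and 1016, with 139 at 0 h, 122, 122, 117 and 134 minus 0 h, and 2 for the slope.

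Leaving out 1 array at a time without the block, where the lone array of a time is assumed to vary like the others, gave 41 (without 10 h replicate 2) to 147 (without 16 h replicate 2) for the mean. The count fell by more than 1.5 times without 4 h replicate 2 (49), 8 h replicate 1 (51), 8 h replicate 2 (74), 10 h replicate 1 (62) and 16 h replicate 1 (71). The ranges were 0 to 70 at 0 h, 0 to 1 at 4 h, 0 to 4 at 8 h, 0 to 1 at 10 h, 0 to 5 at 16 h and 0 to 14 for the slope. They were 0 to 53, 0 to 56, 0 to 53 and 0 to 48 for 4, 8, 10 and 16 h minus 0 h, and 0 to 1 for 8 h minus 4 h and for 10 h minus 8 h. The highest counts at 0 h and minus 0 h came without 0 h replicate 2. Orientation aside, GP011D5 and GP062A4 stayed past the threshold in 30 of 30 alternatives, GP120H2 in 29 and GP001F5 in 19. Some of these 30 gave the same result for the mean, as said above, so that the separate checks are fewer. The mean of all probes of a gene and the gene lists were not run, since no probe is paired with a gene.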

Other observations

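All tests in this part were chosen after the results were seen. The first pattern in this part is the 189 probes called for the mean of 4 to 16 h. Of the 35 splits of the 8 treated arrays into 4 and 4, only the real one, in a simpler fit of the deposited values, called as many probes, 1509 against a highest of 0 in the others. This is not the fit that gave the 189, and 1 of 35 is the smallest share possible. The real split is the array number, whose arrays were already seen to correlate, and every other split mixes the numbers. The count thus restates those correlations, and says nothing on whether treatment or orientation lies behind it. A dye effect peculiar to the arrays numbered 2 stays open as part of the cause. On its own it would leave the called probes near 0 on the arrays numbered 1, where their treated median was 0.241. The fit picks probes on which the 2 arrays of a time agree, so that this level is partly set by the picking. On the second 0 h array the called probes had a median of -0.0203 on their side, with quartiles of -0.127 and 0.0620, against a treated median of 0.241 on the arrays numbered 2, but it is the only 0 h array of that number. It also correlated more with treated arrays numbered 2 (0.397 to 0.473) than with those numbered 1 (0.242 to 0.265). The covariance was higher by 0.00119, so that some effect of number 2 may be present at 0 h. Print pin classes, read from repeating positions of the wells, held 7.51% to 21.3% of the variance on arrays numbered 2. On arrays numbered 1 they held 1.68% to 6.07%. An effect of position may thus enter the correlations among arrays numbered 2, and it was not removed from them. The covariance of the second 0 h array with number 1 was also taken as the shared dye effect. The treated arrays then held a part of opposite sign on the 2 numbers at 0.00378. Parts peculiar to number 1 and to number 2 came to 0.00336 and 0.00126. All these parts rest on that single 0 h array. A shift shared by a print pin class or a plate is argued against, since 172 probes (91.0%) stayed called after centring by both, while an effect of position on a smaller scale stays open. A dye effect peculiar to the arrays numbered 1 cannot be told apart from treatment either: the median was -0.00983 on the first 0 h array, but that array does not carry the dye effect that the others share. On its own such an effect would leave the arrays numbered 2 near 0, where the treated median was 0.241, a level also partly set by the picking. An effect of the steroid may account for part of the 189 and remains a hypothesis.

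The 13 probes were found in steps. First, 14 probes were taken that were at least 2-fold on 1 side on both 0 h arrays. Then probes on 1 side at all 4 treated times were taken with a smallest size of 0.2 (54 probes), 0.25 (22 probes) and 2-fold (15 probes), and of the last the 13 with 1 sign on both 0 h arrays were kept. Of these 13, 11 are also among the 14, so that tests on the 14 and on the 13 use largely the same probes. A change caused by the steroid as the whole cause is argued against for the 13, since their log ratio on the second 0 h array had a median size of 0.616, with quartiles of 0.456 and 0.725, and quartiles of 0.502 and 0.767 on the first. The size does not depend on the sign of that array. The test was first run over all 15, with a median size of 0.530 and quartiles of 0.313 and 0.716, and was moved to the 13 after that value was seen, because the argument rests on the ratio at 0 h. The 13 were picked by their shared sign at 0 h. The remaining 2 of the 15, GP011D5 at 0.0887 and 1 other at -0.154 on the second 0 h array, are not covered by this. For the 14 probes picked from the 0 h arrays alone, the ratio of the 4 h to the 16 h value had a median of 1.09, with quartiles of 0.987 and 1.18. For the 180 called probes outside the 13 it was 0.570, with quartiles of 0.399 and 0.799. The ratio of the 14 goes with material added at a fixed ratio, such as a control transcript, to 1 labelling. Addition to the same sample at all times does not, however, give the 13 their shared sign at 0 h, unless the sign of the first 0 h array is turned. Which material the wells hold is open, since the files do not say.

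Of the 180 other called probes, 18 have a called probe of the same side in the next well. In 1000 shuffles within plates the median was 4 and the highest 16 (permutation p = 0.001, the smallest that 1000 shuffles can give). Of the 180, 37 lie in plates 1 to 11, which hold 1032 of the 10523 tested probes, an excess noticed after the values were seen. Position and related clones in neighbouring wells were not told apart by any test.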
